A study of Danio rerio with 15 samples.

How the data were processed

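Gene expression was measured by RNA sequencing in 15 zebrafish libraries, 7 from NRAS-driven brain tumors and 8 from normal brain. Per the labels, dissected tissue was kept in RNAlater and frozen, RNA was isolated with RNeasy kits, libraries were made with the TruSeq RNA v2 kit after oligo dT selection, and single reads of 50 cycles were taken on an Illumina HiSeq. Per the submitters' processing notes, Novoalign 2.08.01 and DESeq2 were used, and their order and settings are not given in the sources used here. The read counter, the genome build and the annotation are not given in the sources used here either, so genes are placed by Ensembl ID and symbol alone.

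The deposited table has 22513 genes and 32 columns of values, all of which were used. Its 15 count columns hold whole read counts per gene, per the file headers, with no normalization. Its 15 FPKM columns are the authors' values per kilobase and per 1000000 counts of the column's own total, which was checked by dividing each count by its FPKM and its column total. That quotient, the gene length, had a coefficient of variation over the libraries of at most 4.99e-05 for 99% of genes. The log2 column is the authors' log2 fold change of tumor over normal brain, and its sign was checked against the counts. The p-value column is the authors' adjusted p-value of that comparison. Every gene in the deposited table has a sum of at least 10 counts over the libraries, so genes below that sum were not analysed here. Of the gene IDs 20915 had a symbol, 1598 had none, and 2918 shared a symbol with another ID, and for these the Ensembl ID is given where a single copy is meant. No pair of libraries held identical counts.

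Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 19260 genes and left out 3253. Library sizes were scaled by the trimmed mean of M-values (TMM), and a quasi-likelihood model with the group as its only term was fitted. Two-sided p-values were adjusted by the method of Benjamini and Hochberg over all tested genes, with a threshold of 0.05. A change of at least 2-fold means an absolute log2 fold change of 1 or more. CPM values use the scaled library sizes, and log2 CPM values carry a prior count of 2. The SE of a log2 fold change was derived as its absolute value divided by the square root of the F statistic of the quasi-likelihood test. A count of 3 was taken as the limit that a count of 0 allows.

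The groups come from the labels. They give no batch and no pairing, since each library has its own number, and the 1 comparison set 7 brain tumors against 8 normal brains. The main tests, the alternatives planned for them, the rule for naming genes and 33 gene lists were fixed before the data were examined. The lists were written from textbook knowledge of cell types and pathways, and 1110 of their 1211 members were found in the deposited table. Each list was tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Each was also tested with fry, and p-values were adjusted over the 33 lists. Members were counted as higher, lower or not past the threshold with adjustment over all genes and with adjustment over the list alone.

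The genes named by rule were, in the first place, NRAS, SOX10 and OLIG2 and list members needed to describe a count of 5 or fewer. To these came the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean of at least 10 CPM in the higher group, no overlap between the groups and a proper symbol. The rule further took the 2 members with the smallest p of each list that passed, in the direction of the list, and the 1 member with the smallest p of every other list.

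The alternatives fixed beforehand were median-ratio (RLE) size factors, upper-quartile factors, library size alone, library size without the 50 genes of largest mean count, no filter, a filter at a mean of 5 CPM, robust dispersions, a covariate for the library numbers, DESeq2 1.42.0, limma-voom with group weights, glmTreat, an estimated correlation in camera, and leaving out each library in turn. Added after seeing the data were fits of libraries 1 to 8 and of 9 to 15 alone, and a fit without 4 libraries that carried transcripts of other tissues or stood apart. The real split of the libraries was set against 99 other splits into groups of the same sizes, drawn with a fixed seed. Libraries far from their group were sought with Dixon's test at the 95% level. The pipeline was tested on simulated data with 18617 genes at the depths and dispersions of these libraries, where it recovered 18% of genes changed 1.5-fold, 60% at 2-fold, 90% at 4-fold and 98% at 8-fold. It called 11 of 18417 unchanged simulated genes, and a simulated list without changes had a camera adjusted p of 0.832. The simulation changed 50 genes at each fold, as many up as down, and gave both groups the same dispersions. In the real comparison 76.9% of genes passed and the coefficient of variation was 0.502 in tumors against 0.233 in normal brain. The simulated rates therefore may not hold for it.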

Results

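Polyadenylated RNA was sequenced from zebrafish brain tumors driven by NRAS, a small GTPase of the Ras family, and from normal zebrafish brain. The tumors are of the type the submitters call CNS-PNET, the primitive neuroectodermal tumor of the central nervous system. The table held 7 brain tumor libraries (numbered 5, 6, 7, 8, 12, 13 and 14) and 8 normal brain libraries (numbered 1, 2, 3, 4, 9, 10, 11 and 15), and the design has 1 comparison, tumor against normal brain. Libraries held 13605588 to 21347976 counts, with 16146867 ± 1312772 (SD, n = 8) in normal brain and 16928015 ± 2485278 (SD, n = 7) in brain tumor. Between 20458 genes (brain tumor 13) and 22185 genes (brain tumor 12) had at least 1 count. At these depths a count of 3 corresponded to between 0.141 and 0.220 counts per 1000000 library counts (CPM), which covers counting error only. These limits use the unscaled library sizes, while the CPM of genes use the scaled ones. The labels do not state that the libraries of a group came from separate fish, so every p-value measures the spread between these samples. Genes named as examples beyond the naming rule given with the methods were chosen after their values were seen.

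Which transcripts distinguish the tumors from normal brain was the question of the comparison. The brain tumors held high levels of cell division genes, of SOX10 and OLIG2, of ribosome synthesis genes and of interferon response and microglial genes, and low levels of neuronal and synaptic genes. SOX10 (ENSDARG00000077467), a transcription factor of the neural crest and of oligodendrocytes, rose from 32.4 ± 2.94 CPM in normal brain to 1321 ± 341 CPM in brain tumor (mean ± SD, n = 8 and 7), a log2 fold change of 5.35 ± 0.18 (SE). OLIG2 (ENSDARG00000040946), which specifies oligodendrocytes and motor neurons, rose from 42.4 ± 5.87 to 436 ± 155 CPM, a log2 fold change of 3.36 ± 0.19. CCNB1, the mitotic cyclin B, rose from 2.02 ± 0.508 to 73.6 ± 17.9 CPM (log2 fold change 5.18 ± 0.20). In the other direction SNAP25 (ENSDARG00000020609), a component of the synaptic vesicle fusion machinery, fell from 4105 ± 247 to 385 ± 335 CPM (log2 fold change -3.41 ± 0.62).

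Of 19260 genes tested with edgeR's quasi-likelihood test, 8370 were higher and 6436 lower in brain tumor at a Benjamini-Hochberg adjusted p below 0.05, and 4454 did not pass. Changes of at least 2-fold were seen in 5254 genes in the higher and 4817 in the lower direction. In 5247 genes every tumor lay above every normal brain and in 4744 genes every tumor lay below, where chance gives 0.0311% of genes for both directions together. The median log2 fold change over all tested genes was 0.21 with the trimmed-mean scaling used here and 0.02 with median-ratio size factors, so small changes depend on the scaling. Normal brain 1 carried liver transcripts, normal brain 2 photoreceptor transcripts and normal brain 4 skin transcripts, and brain tumor 13 stood apart from the other tumors. With these 4 libraries in doubt left out, a choice made after seeing the data, 8077 genes were higher and 6216 lower. This fit is one-sided for other tissues, since it kept brain tumor 6, with the highest photoreceptor mean of the tumors, brain tumor 12, with the highest skin mean of all libraries, and brain tumors 5, 6, 12 and 14, with muscle list means above every normal brain. The first principal component took 74.3% of the variance and separated the groups, and the second took 8.0%. Brain tumor 13 had a score of 232.5 on the first and -119.5 on the second. The tumors varied more among themselves than the normal brains did, with a biological coefficient of variation of 0.502 against 0.233.

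**Figure D1:**
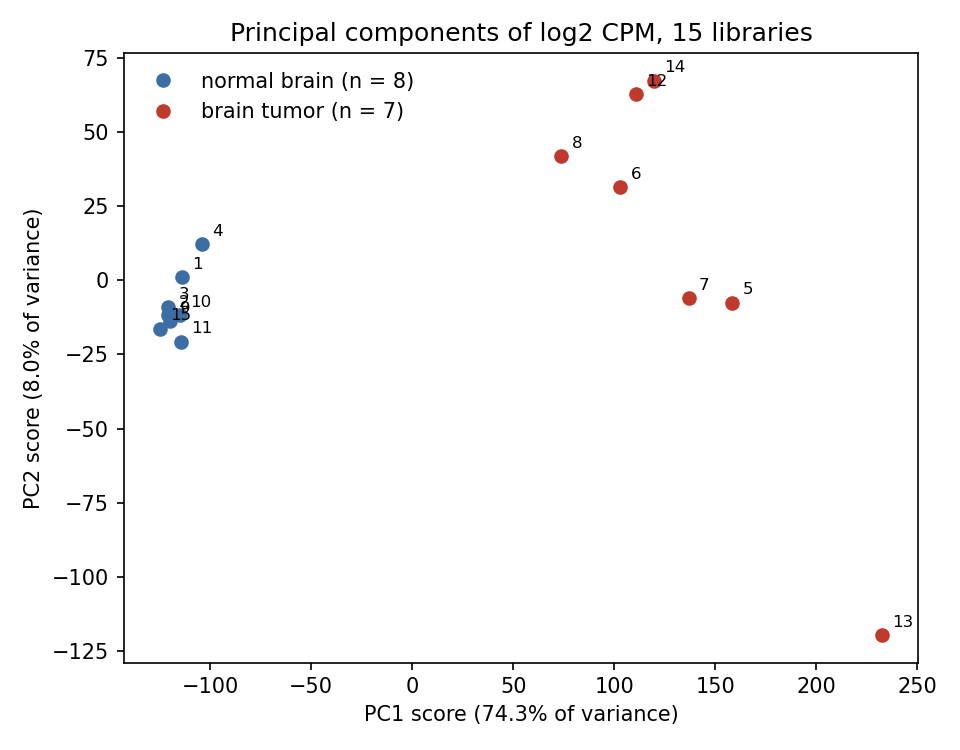
Scores of the 15 libraries on principal components 1 and 2 of log2 CPM, with 74.3% and 8.0% of the variance on the axes. The 8 normal brains (blue) sit together on the left, and among the 7 tumors (red, each with its number) brain tumor 13 lies at the lower right, away from the other 6.

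NRAS (ENSDARG00000038225), the gene named as the driver, rose from 8.82 ± 1.04 to 29.5 ± 8.02 CPM (log2 fold change 1.74 ± 0.15, adjusted p = 3.07e-08), and every tumor lay above every normal brain. Left out 1 at a time, the libraries gave NRAS log2 fold changes of 1.54 to 1.81. Whether reads of a transgene were assigned to this gene is not given in the sources used here. Among 27 Ras pathway components 13 rose, 8 fell and 6 did not pass. RASA1 (ENSDARG00000035535), a GTPase-activating protein that switches Ras off, rose by a log2 fold change of 1.36 ± 0.10, and PTPN11, the phosphatase SHP2 upstream of Ras, rose by 1.73 ± 0.13. The Raf and MEK kinase genes BRAF and MAP2K1 fell, with log2 fold changes of -1.72 ± 0.16 and -1.78 ± 0.18. The components had a median log2 fold change of 0.04 and did not pass the set test (camera adjusted p = 0.66). Of 34 feedback and target genes of the Ras-MAPK cascade 15 rose, 8 fell and 11 did not pass, with a median of 0.25 and a camera adjusted p of 0.676. Rising members included ETV4, an ETS transcription factor (4.64 ± 0.34), the feedback inhibitor SPRY4 (2.55 ± 0.24) and the ERK phosphatase DUSP6 (1.11 ± 0.16). The immediate early gene FOSB fell (-3.86 ± 0.25), as did etv5a (-1.93 ± 0.15). Brain tumor 13 had the highest mean of this list among the tumors, 5.51 log2 CPM against 4.92 to 5.13 in the other 6.

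Oligodendrocyte precursor genes moved in both directions, 13 of 27 rising, 9 falling and 5 not passing. Among the increases, ERBB3 (ENSDARG00000006202), a neuregulin receptor of glia, rose from 6.25 ± 0.848 to 536 ± 177 CPM (log2 fold change 6.42 ± 0.22). GPR17, a receptor of committed precursors, rose by 5.30 ± 0.39, and SOX9 (ENSDARG00000043923), a glial transcription factor, by 5.33 ± 0.19. The proteoglycan gene NCAN and the receptor phosphatase PTPRZ1 (ENSDARG00000051814) fell, with log2 fold changes of -4.18 ± 0.39 and -2.67 ± 0.44, and PDGFRA, the growth factor receptor of these precursors, did not pass (8.06 against 10.4 CPM, adjusted p = 0.342). CSPG4, olig1, bcan and 1 copy of SOX8 (ENSDARG00000105301) did not pass either. The list passed the set test (median 1.04, camera adjusted p = 0.00167), with adjusted p = 0.471 with an estimated correlation and 0.0999 in limma-voom with group weights. Brain tumor 13 had a list mean of 4.09 log2 CPM, below the other tumors (5.18 to 5.73) and below every normal brain (4.24 to 4.44).

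Myelin genes, those of the membrane sheath that mature oligodendrocytes wrap around axons, followed with 19 of 27 members higher, 5 lower and 3 not passing. UGT8, which makes the myelin lipid galactosylceramide, rose from 91.5 ± 8.82 to 1135 ± 334 CPM (log2 fold change 3.63 ± 0.18). MYRF, a transcription factor of myelination, rose by 2.31 ± 0.19. Of the duplicated myelin basic protein genes mbpb rose (2.64 ± 0.33) and mbpa fell (-1.06 ± 0.20). The other decreases were in CNTN1, s1pr5a, 1 copy of GPR37 (ENSDARG00000033296) and 1 copy of GJD2 (ENSDARG00000067999), and the other GJD2 copy, cd9a and ASPA did not pass. The camera adjusted p was 0.0545, so the list did not pass, with a median of 1.55 and an adjusted p of 0.531 with an estimated correlation. It did pass with median-ratio size factors (adjusted p = 0.0303), with DESeq2 (0.0167), with limma-voom (0.0451), with upper-quartile factors (0.0429), with library size alone (0.0287) or without the 50 largest genes (0.0372), with no filter (0.0297) and in libraries 9 to 15 alone (0.0279), a grouping by number chosen after seeing the data. It also passed without normal brain 1 (0.0497), 4 (0.043) or 11 (0.0481) and without brain tumor 5 (0.0465), 8 (0.0081) or 14 (0.0292).

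**Figure D2:**
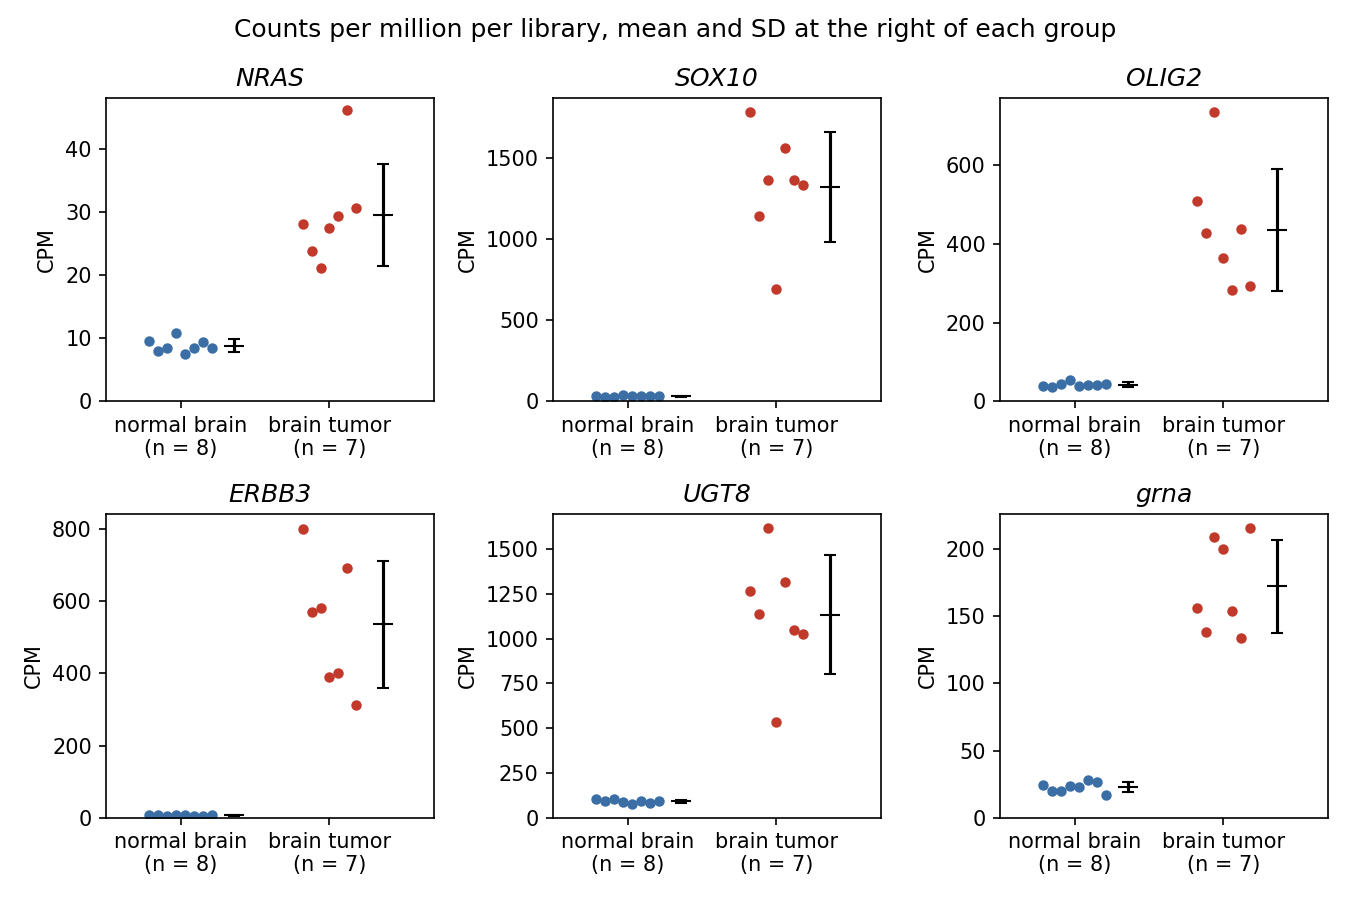
CPM of NRAS, SOX10, OLIG2, ERBB3, UGT8 and grna in each library, with 8 normal brains in blue and 7 brain tumors in red on a linear axis that starts at 0. The bar beside each group is the mean with the SD, and in all 6 genes every tumor lies above every normal brain.

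Cell cycle genes rose nearly without exception, 52 of 53, and only CCND1, the G1 cyclin D, did not pass (adjusted p = 0.114). TYMS, the enzyme that makes thymidylate for DNA synthesis, rose from 2.8 ± 0.555 to 63.8 ± 14.4 CPM (log2 fold change 4.50 ± 0.17). The mitotic kinase CDK1 rose by 6.04 ± 0.37 and the proliferation marker mki67 by 4.65 ± 0.29. The median of the list was 4.36, with a camera adjusted p of 1.15e-38 and adjusted p = 0.13 with an estimated correlation. Ribosome biogenesis genes and other targets of MYC, a transcription factor of growth, rose in 49 of 51 cases. The exceptions were CTPS1 (ENSDARG00000098386), a CTP synthase that fell (-0.91 ± 0.26), and the spermidine synthase SRM, which did not pass (adjusted p = 0.856). NHP2 and DKC1, proteins of the complexes that modify ribosomal RNA, rose by 2.62 ± 0.09 and 3.0 ± 0.12. The list had a median of 1.76 (camera adjusted p = 4.95e-19, adjusted p = 0.422 with an estimated correlation). MYC itself is duplicated, and both copies rose, ENSDARG00000045695 by 3.41 ± 0.24 and ENSDARG00000007241 by 1.82 ± 0.22, whereas MYCN fell (-1.98 ± 0.23).

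Neuronal transcripts fell as a group. Among 40 pan-neuronal genes 38 fell, with a median log2 fold change of -3.12, an 8.7-fold decrease. DNM1 (ENSDARG00000009281), a GTPase of synaptic vesicle recycling, fell from 145 ± 13.5 to 30.2 ± 8.05 CPM (-2.27 ± 0.15), and the vesicle protein gene vamp2 fell, at a log2 fold change of -1.97 ± 0.15. The neurexin gene nrxn1b rose (1.11 ± 0.25) and SNCG did not pass (0.76 ± 0.51). Glutamatergic synapse genes fell in 38 of 39 cases (median -3.32), among them the scaffold gene SHANK3 (-3.01 ± 0.25) and DLG2 (-2.07 ± 0.16), and the receptor subunit gene gria4a rose (0.70 ± 0.27). GABAergic synapse genes fell in 31 of 32 cases (median -3.30), among them GPHN (ENSDARG00000089076), which anchors GABA receptors at the synapse (-2.06 ± 0.12). One copy of DLX2 (ENSDARG00000017174), a transcription factor of inhibitory neurons, did not pass (-1.10 ± 0.62). The 3 lists had camera adjusted p-values of 4.95e-10, 2.04e-10 and 4.71e-10, in that order. They did not pass with an estimated correlation (adjusted p = 0.471, adjusted p = 0.474 and adjusted p = 0.471).

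Regional and peptidergic neuronal genes fell likewise. Neuropeptide and hypothalamic genes fell in 33 of 35 cases (median -2.83, camera adjusted p = 9.98e-06, adjusted p = 0.474 with an estimated correlation), including kiss2, which encodes kisspeptin (-4.89 ± 0.54), and the enkephalin precursor gene penka (-3.49 ± 0.44), while gnrh3 rose (0.83 ± 0.23) and crha did not pass. Cerebellar genes fell in 27 of 28 cases (median -3.37, camera adjusted p = 2.23e-06, adjusted p = 0.531 with an estimated correlation). Examples were ALDOC (ENSDARG00000019702), an aldolase of Purkinje cells and astroglia (-2.46 ± 0.19), and RORA, a transcription factor of Purkinje cells (-2.59 ± 0.24), and the exception was a copy of the calcium channel gene ITPR1 (ENSDARG00000014655), which rose (0.62 ± 0.17). Telencephalic and tectal genes fell in 33 of 35 cases (median -3.10, camera adjusted p = 2.95e-06, adjusted p = 0.474 with an estimated correlation). EOMES (ENSDARG00000104243) and LHX2, transcription factors of the developing forebrain, fell, at -4.12 ± 0.44 and -3.67 ± 0.41, and GATA2 and tbr1a did not pass. Brain tumor 13 was the lowest of the tumors in all 6 of these lists, with a pan-neuronal mean of 2.87 log2 CPM against 4.51 to 6.32 in the other tumors and 8.22 to 8.38 in normal brain.

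**Figure D3:**
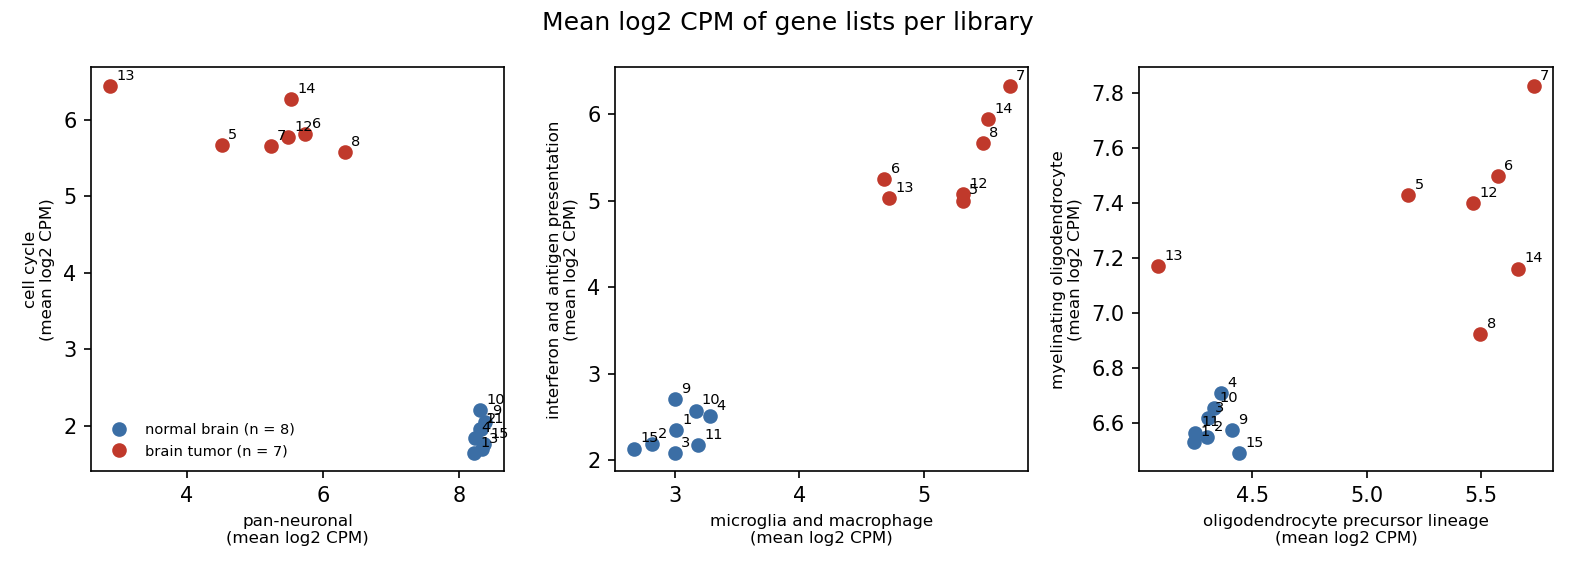
Mean log2 CPM of 6 gene lists in each library, drawn as 3 pairs of lists, with 8 normal brains in blue, 7 brain tumors in red and library numbers beside the points. The tumors have cell cycle means of 5.58 to 6.44 and pan-neuronal means of 2.87 (brain tumor 13) to 6.32 in the left panel, the middle panel shows microglial against interferon genes, and the right panel oligodendrocyte precursor against myelin genes.

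Radial glial, progenitor and patterning genes split. Among 31 radial glia and astroglia genes 6 rose and 16 fell. GFAP, the intermediate filament of astroglia, rose (2.92 ± 0.51), whereas the gap junction gene GJA1 (-2.56 ± 0.56) and the glutamate transporter gene SLC1A2 (-1.02 ± 0.19) fell (median -0.44, camera adjusted p = 0.0553, 0.0287 with no filter, 0.0126 in limma-voom and 0.0379 in libraries 1 to 8 alone). Neural stem and progenitor genes rose in 11 and fell in 23 of 42 cases (median -0.65, camera adjusted p = 0.272). SOX2, a transcription factor of neural stem cells, rose from 58.3 ± 4.23 to 531 ± 121 CPM (3.19 ± 0.14), and hmga1a, a chromatin protein of proliferating cells, by 3.25 ± 0.16, whereas SOX11 (ENSDARG00000095743), a transcription factor of immature neurons, fell (-1.98 ± 0.24). Hedgehog pathway genes rose in 1 and fell in 5 of 11 cases, with GLI2 (ENSDARG00000020884), a transcription factor of the pathway, at -2.63 ± 0.25 and the pathway antagonist HHIP at -2.91 ± 0.32. GLI1, GLI3 and CDON also fell, and PTCH1, SMO, BOC, foxf2a and the other GLI2 copy did not pass (median -0.40, camera adjusted p = 0.18). Wnt pathway genes rose in 3 and fell in 10 of 18 cases (median -1.04, camera adjusted p = 0.255). TCF7L1 (ENSDARG00000038159), a repressor of Wnt targets, its duplicate tcf7l1b and the secreted Wnt inhibitor dkk1a rose (2.76 ± 0.13, 1.96 ± 0.22 and 5.70 ± 0.72), the target gene AXIN2 fell (-1.95 ± 0.22), and WIF1, ZNRF3, AXIN1, SFRP1 and NKD2 did not pass. DNA damage response genes rose in 13 and fell in 6 of 28 cases (median 0.39, camera adjusted p = 0.18). BAX, a mediator of apoptosis, rose (2.07 ± 0.11), and the cell cycle inhibitor cdkn1a and the ubiquitin ligase mdm2 did not pass (adjusted p = 0.577 and 0.616).

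Microglial and interferon response genes rose. Of 46 microglia and macrophage genes 43 rose, none fell, and mhc2dab, csf1rb and apoc1 did not pass. The progranulin gene grna rose from 22.8 ± 3.79 to 173 ± 34.7 CPM (log2 fold change 2.92 ± 0.15), and c1qc, a chain of the first complement component, by 4.37 ± 0.28. The list had a median of 2.42 (camera adjusted p = 1.02e-08, adjusted p = 0.471 with an estimated correlation). Interferon response and antigen presentation genes rose in 37 of 38 cases (median 3.12, camera adjusted p = 2.43e-11, adjusted p = 0.471 with an estimated correlation), and mhc1uba did not pass. The cytokine signaling inhibitor SOCS3 rose by 2.42 ± 0.12, the interferon signaling factor irf9 by 3.18 ± 0.19 and the ubiquitin-like isg15 by 6.05 ± 0.58. Neutrophil genes rose in 12 of 13 cases (median 1.75, camera adjusted p = 0.18), including the matrix protease MMP9 (3.83 ± 0.28), and NCF4 fell (-1.23 ± 0.24). This list passed without the 4 libraries in doubt (median 1.94, camera adjusted p = 0.0404). Brain tumor 13 had the lowest neutrophil mean of the tumors, 2.0 log2 CPM against 3.03 to 3.72. Among 32 T, NK and B cell genes 19 rose and 8 fell (median 1.08, camera adjusted p = 0.576). Increases included the B cell adaptor blnk (3.38 ± 0.29) and ighm, the immunoglobulin M heavy chain (4.84 ± 0.54), and the falling members EOMES (ENSDARG00000104243, -4.12 ± 0.44), bcl11ba (-3.61 ± 0.44) and GATA3 (-2.46 ± 0.48) are also transcription factors of neurons. SYK, il2rb, CCR7, RAG1 and RAG2 did not pass.

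Vascular genes did not move together. Endothelial genes rose in 9 and fell in 15 of 40 cases, with EGFL7, a secreted endothelial factor, rising (2.0 ± 0.19) and the receptor genes flt1 (-1.11 ± 0.23) and kdrl (-0.72 ± 0.24) falling (median -0.20, camera adjusted p = 0.435). Mural cell genes rose in 7 and fell in 7 of 23 cases. The transcription factor gene foxc1b rose (2.93 ± 0.31) and the pericyte channel gene ABCC9 fell (-2.23 ± 0.33). The median of this list was 0.34 and its mean 0.21, while the camera test pointed down (adjusted p = 0.615). Extracellular matrix and meningeal genes rose in 40 and fell in 8 of 69 cases (median 1.12, camera adjusted p = 0.272, and 1.75e-05 in libraries 9 to 15 alone). The list mean was 3.99 to 4.98 log2 CPM in brain tumors 5, 6, 12 and 14, the tumors with muscle list means above every normal brain, and 2.77 to 3.13 in brain tumors 7, 8 and 13, against 3.67 in normal brain 4 and 3.46 in normal brain 1, the highest of the normal brains. MMP14 (ENSDARG00000008388), a membrane-bound matrix protease, rose from 18.6 ± 3.23 to 541 ± 227 CPM (4.86 ± 0.27), the collagen gene col1a1a rose (2.74 ± 0.76), and the glial matrix gene TNC (ENSDARG00000021948) fell (-3.06 ± 0.43).

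Several lists stood for other tissues that dissection of a brain can carry along. Skeletal muscle genes rose in 18 and fell in 1 of 31 cases (median 1.87, camera adjusted p = 0.576), including the calcium pump gene atp2a1 (4.32 ± 0.99) and ckma, muscle creatine kinase (3.67 ± 1.0). The falling member was RYR1 (ENSDARG00000023797, -3.48 ± 0.46), a calcium release channel also present in neurons. Brain tumors 5, 6, 12 and 14 had muscle list means of 4.33 to 5.22 log2 CPM, against 0.38 to 1.62 in the other 3 tumors and 1.12 to 3.21 in normal brain. Libraries 1 to 8 alone gave this list a median of 0.73, and libraries 9 to 15 alone gave 3.46 (camera adjusted p = 0.00907). Skin epithelium genes rose in 7 of 27 cases, or in 3 adjusted over the list alone, none fell, and the median was 0.65 (camera adjusted p = 0.798). ECRG4, a secreted peptide precursor, rose by 5.49 ± 0.49. Normal brain 4 and brain tumor 12 had skin list means of 5.18 and 5.66 log2 CPM, the highest of their groups. Without brain tumor 12 the skin median was -0.31 and the camera direction turned downward. The fit without the 4 libraries in doubt leaves out normal brain 4 but keeps brain tumor 12, and there 19 skin genes rose and the median was 1.94. Photoreceptor genes rose in 2 and fell in 3 of 16 cases (1 rose adjusted over the list alone, median -1.31, camera adjusted p = 0.328), with the cone gene GNAT2 falling (-2.92 ± 0.46) and copies of RPE65, the isomerase of the visual cycle in pigment epithelium, rising (ENSDARG00000007480 by 2.85 ± 0.74 and ENSDARG00000094752 by 0.93 ± 0.36). The photoreceptor gene rom1a and rlbp1b, a retinoid-binding protein gene, also fell. Normal brain 2 (3.61 log2 CPM) and brain tumor 6 (2.52) had the highest photoreceptor means of their groups, and the median was -0.14 without normal brain 2, -2.30 without brain tumor 6 and 0.03 with a filter at a mean of 5 CPM. Normal brain 1 held transcripts of liver plasma proteins, with the apolipoprotein gene apoa1b at 3631 CPM against at most 9.81 CPM in the other normal brains.

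Pituitary genes rose in 3 and fell in 6 of 11 cases (median -0.68, camera adjusted p = 0.18). The glycoprotein hormone genes CGA (3.28 ± 1.32) and lhb (2.79 ± 1.22) rose, PCSK1, a prohormone convertase gene, fell (-3.93 ± 0.50), and EYA1 did not pass. The median was 0.63 without the 4 libraries in doubt, 0.50 with a filter at a mean of 5 CPM, and 0.55, 0.54 and 0.34 without brain tumor 7, 8 or 13 alone. Erythrocyte genes fell in 12 of 19 cases (median -1.06, camera adjusted p = 0.0298, adjusted p = 0.533 with an estimated correlation). The largest decreases were of the copies of ANK1 (ENSDARG00000074777, -3.65 ± 0.43, and ENSDARG00000059093, -3.40 ± 0.43), an ankyrin also present in neurons, the globin gene hbaa1 fell, at a log2 fold change of -1.06 ± 0.31, and UROD, an enzyme of heme synthesis, rose (1.3 ± 0.15). This call was lost with DESeq2 (adjusted p = 0.0541), with a filter at a mean of 5 CPM (0.0605), in libraries 9 to 15 alone (0.0697) and without the 4 libraries in doubt (0.0508). Ependyma and choroid plexus genes fell in 21 of 33 cases, or in 20 adjusted over the list alone (median -1.0, camera adjusted p = 0.00709, adjusted p = 0.613 with an estimated correlation), and the call was lost with the filter at 5 CPM (adjusted p = 0.147). The growth factor binding protein gene IGFBP2 (ENSDARG00000031422) and foxj1b, a regulator of motile cilia, fell, at -2.29 ± 0.25 and -2.30 ± 0.29, and RFX4 rose (1.82 ± 0.33). Neural crest and pigment cell genes rose in 10 and fell in 4 of 23 cases (median 0.53, camera adjusted p = 0.576). SOX10 belongs to this list as well, FOXD3, a neural crest transcription factor, rose by 5.40 ± 0.87, and TFAP2A (-3.02 ± 0.46), OCA2, ltk and aox5 fell.

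Hypoxia and glycolysis genes moved both ways. Of 52 hypoxia and glycolysis genes 14 rose, 27 fell and 11 did not pass (median -0.59, camera adjusted p = 0.0296, adjusted p = 0.474 with an estimated correlation). The glycolytic enzyme genes HK1 and PFKP (ENSDARG00000028000) fell, at -1.55 ± 0.09 and -2.27 ± 0.16, and HK2, the inducible hexokinase, rose (3.64 ± 0.31), as did a copy of the angiogenic factor VEGFA (ENSDARG00000034700, 2.16 ± 0.18). This call was lost without brain tumor 7 (adjusted p = 0.053), without brain tumor 14 (0.0505), in libraries 9 to 15 alone (0.111) and without the 4 libraries in doubt (0.054). Heat shock and unfolded protein response genes rose in 30 and fell in 6 of 43 cases (median 0.81, camera adjusted p = 0.0565). EDEM1, which helps to clear misfolded proteins, and HSPA5, the chaperone of the endoplasmic reticulum, rose (1.83 ± 0.11 and 1.22 ± 0.14), and BAG3 fell (-1.76 ± 0.18). The list passed with no filter (adjusted p = 0.0366) and in limma-voom (0.033). Apart from the counts given for the skin, photoreceptor and ependyma lists and for endothelium, where 14 genes fell, the counts adjusted over the list alone equalled those over all genes. In total 5 lists passed the camera test upward and 9 downward, and 0 of the 33 passed in camera with an estimated correlation. With that correlation 3 lists had an unadjusted p below 0.05, which were cell cycle (0.00393), ribosome biogenesis (0.0256) and oligodendrocyte precursor (0.0478). In fry, which asks whether the genes of a list move one way on balance without comparing them to other genes, 28 of the 33 lists had an adjusted p below 0.05. Of these, 14 had not passed in camera, among them Ras pathway components at a median of 0.04 (fry adjusted p = 0.000128), so fry set few lists apart.

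**Figure D4:**
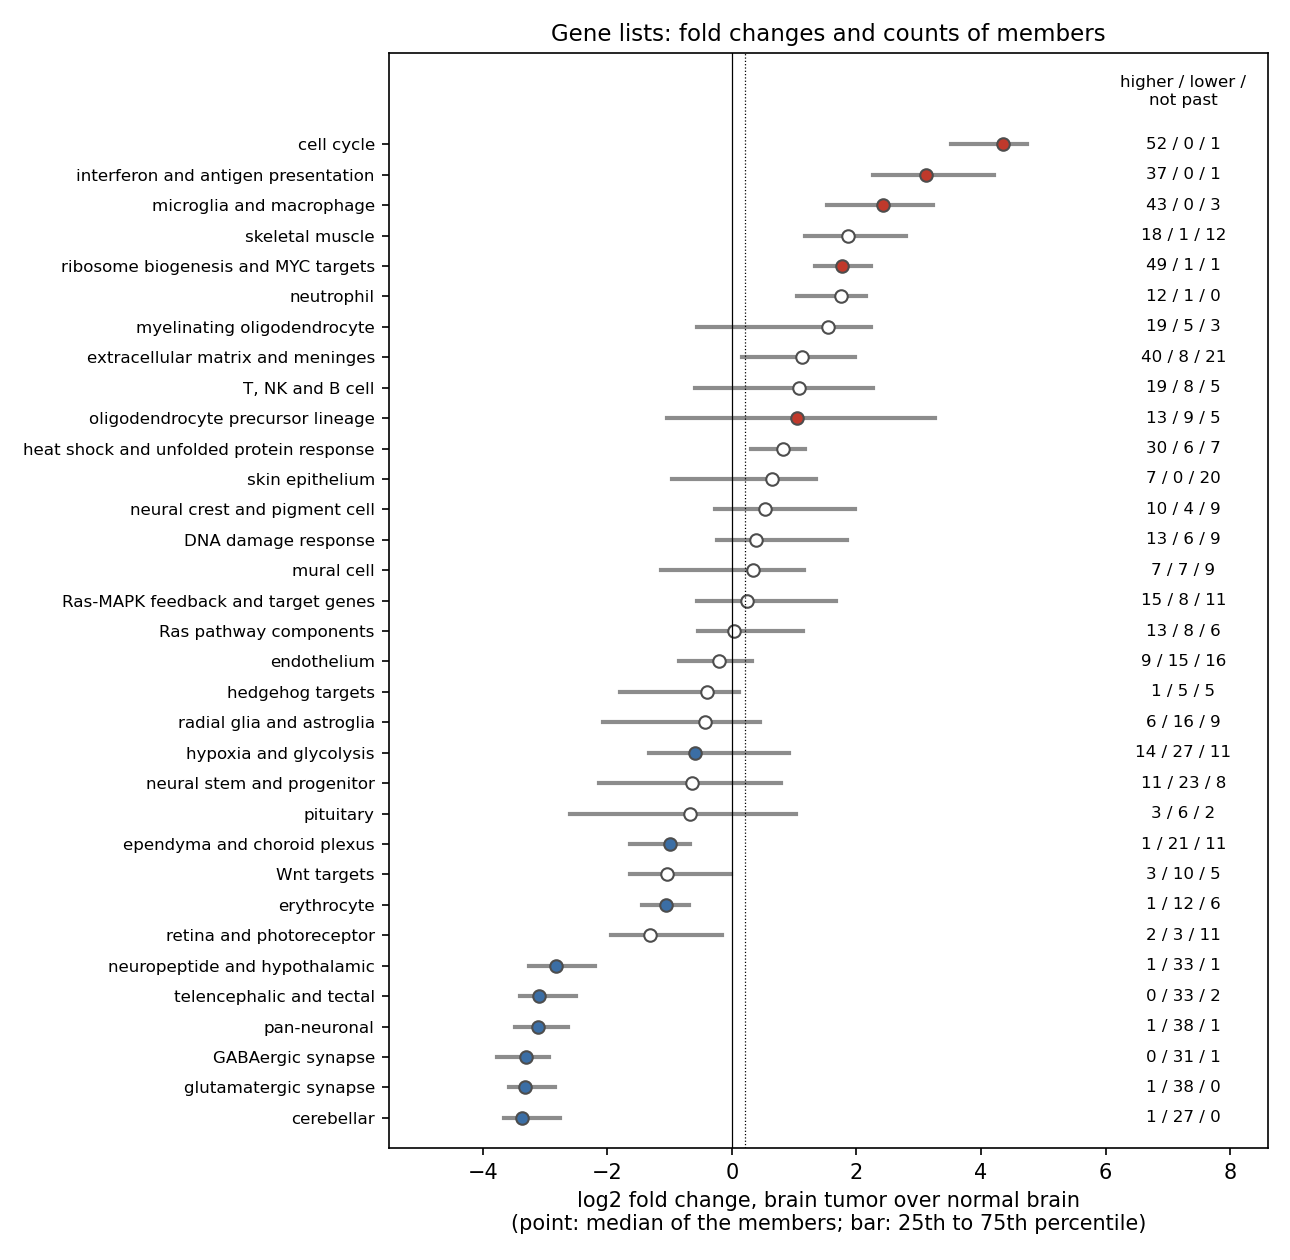
Log2 fold change of the 33 gene lists, brain tumor over normal brain, with the median of the members as a point, a bar over the middle quartiles, and the members higher, lower and not past at the right. Filled points (red up, blue down) passed the camera test with its preset correlation, open points did not, and the dotted line marks the median of all tested genes, 0.21.

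Of the 8 largest increases among genes named by rule, the NK-lysin gene nkl.2, which encodes an antimicrobial peptide of lymphocytes, rose by a log2 fold change of 9.24 ± 1.44. It reached 1647 CPM in brain tumor 8, and without that library the log2 fold change was 6.57. The muscle-type sodium channel gene scn4ab rose by 7.64 ± 1.27, with 4026 CPM in brain tumor 14 and 9.55 CPM in brain tumor 7, and by 5.93 without brain tumor 14. The chemokine gene ccl34b.8 rose by 6.75 ± 1.08, and by 4.65 without brain tumor 8. The complement gene c6.1 (7.40 ± 0.51), the interferon-induced genes ifit8 (7.30 ± 0.62) and gig2e (6.95 ± 0.54), the secreted matrix protein gene CTHRC1 (ENSDARG00000001971, 7.21 ± 0.56) and znf488, an oligodendrocyte transcription factor (6.71 ± 0.23), made up the other increases. In normal brain c6.1, ifit8, gig2e and ccl34b.8 had means of 0.305, 0.175, 0.215 and 0.110 CPM. These lie near the 0.141 to 0.220 CPM of a count of 3, so the sizes of these increases are uncertain. Largest among the decreases was pth2, a neuropeptide gene (-6.28 ± 0.59, and -7.86 without brain tumor 8). Its mean in brain tumor, 0.321 CPM, was also near that level. NPAS4, a transcription factor induced by neuronal activity, fell in both copies (ENSDARG00000055752, -5.24 ± 0.53, and ENSDARG00000087753, -4.72 ± 0.53). The Nogo receptor gene rtn4rl2a (-4.82 ± 0.39), the calcium channel gene CACNA1I (-4.54 ± 0.39), the GABA receptor gene GABRA6 (-4.52 ± 0.59, and -5.39 without brain tumor 8), ANKRD34B (ENSDARG00000077086, -4.37 ± 0.40) and pclob, a presynaptic scaffold gene (-4.37 ± 0.48), completed the decreases.

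The authors' deposited table called 8275 genes higher and 7974 lower at an adjusted p below 0.05. Of the genes tested here, 13727 were called in the authors' deposited table and in the edgeR test, and 13725 of these had the same direction. The exceptions were c3a.1, a complement gene of the liver, at -5.52 ± 1.97 in edgeR and 1.68 in the deposited table, and the yolk precursor gene vtg1, at 3.44 ± 1.40 and -2.18. Without normal brain 1, which held the liver transcripts, c3a.1 had a log2 fold change of 1.93. Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of edgeR had a Pearson correlation of 0.991. The authors' deposited table gives NRAS a log2 fold change of 1.54, SOX10 5.12 and OLIG2 3.14.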

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

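The tests of muscle tissue, of dilution and of scaling, and the choice of liver markers, came only after the result they measure was seen, while that of gene length came before. Dixon's test looks for a library far from the rest of its group and picks out about 1 group in 20 by chance. Among 196 groups of libraries looked at, 28 had such a library, where chance gives 9.8. Brain tumor 13 accounted for 14 of the 28.

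Liver-type transcripts were high in normal brain 1. There apoa1b reached 3631 CPM and tfa, the transferrin gene, 3213 CPM, against at most 9.81 and 9.29 CPM in the other normal brains, and without this library the log2 fold change of apoa1b went from -7.10 to -1.23 (adjusted p = 0.122). RNA of liver tissue in this library is a candidate explanation. Among tested genes 6 of 12 other liver markers that reached 5 CPM were at least 10-fold above the highest other normal brain. Those 12 could not decide, because the filter keeps genes with counts in several libraries and so leaves out genes high in 1 alone. Over all genes of the deposited table, a widening made after the 6 of 12 were seen, 31 of 39 met this bound (79.5%). No biological explanation was tested.

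The muscle-type sodium channel gene scn4ab was above every normal brain (at most 6.57 CPM) in 7 of 7 tumors, from 9.55 CPM in brain tumor 7 to 4026 CPM in brain tumor 14, a separation that the rule by which it was named required. Skeletal muscle tissue may account for part of it in brain tumors 5, 6, 12 and 14, the 4 of the 7 tumors with a muscle list mean above every normal brain. It is argued against in brain tumors 7, 8 and 13, where the median log2 ratio of the muscle genes to normal brain was -1.81, -1.09 and -0.26 (SD over the genes 1.62, 1.21 and 2.62) against 1.46, 2.68 and 5.39 for scn4ab, and normal brains 3 and 4, with higher muscle means than these, had 1.06 and 5.50 CPM of scn4ab. The SD of scn4ab around the muscle list mean was 2.19 over the 7 tumors, against a median of 1.07 and a 95th percentile of 2.19 for the 31 muscle genes, of which 2 varied more, and over tumors 5, 6, 12 and 14 alone it was 2.87 against a 95th percentile of 2.35, with 1 muscle gene varying more. In these 4 tumors muscle tissue and expression by other cells cannot be told apart, since the value over the 7 tumors lies at the bound set for it and 4 libraries are few, and no biological explanation was tested.

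Pan-neuronal genes fell in the tumors, and 3 technical sources of the size of that fall were tested. The choice among the scalings run is argued against by a median log2 fold change of -3.05 to -3.29 over them. Each of these scalings works on the counts of the libraries alone, so a difference in RNA amount per cell could not show in them. Gene length is argued against by a median of -3.27 after the trend over length was removed. A dilution of all neuronal transcripts by exactly 1 common factor in each tumor, with no other source of them, was also tested. It is argued against by the spread of the members' log2 ratios to normal brain. Their SD had a median of 1.31 over the tumors (0.611 to 2.86). In single normal brains, where the median ratios were only -0.17 to 0.11, it was 0.128 to 0.317. The spread cannot decide on an equal loss of all neurons, since other cells in a tumor may express some members. Such an equal loss, a loss of some kinds of neurons more than others, or lower expression within neurons, may remain. The group itself is the only biological difference that the design names.

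Brain tumor 13 had the fewest genes with a count, 20458 against 21472 to 22185 in the other tumors. Its mean log2 CPM was 5.51 for the Ras-MAPK feedback and target list (4.92 to 5.13 in the other tumors), 4.09 for the oligodendrocyte precursor list (5.18 to 5.73) and 2.63 for the neural stem list (3.62 to 4.30). It was -0.0423 for the glutamatergic list (2.25 to 3.79), -0.67 for the GABAergic list (1.64 to 2.84) and -1.51 for the neuropeptide list (0.61 to 1.98). It was 1.21 for the Wnt list (2.39 to 3.09) and 2.0 for the neutrophil list (3.03 to 3.72). In single genes brain tumor 13 had 0.80 log2 CPM of NPAS4 (ENSDARG00000055752, 3.05 to 4.46 in the other tumors), -3.05 of ANKRD34B, the value that a count of 0 takes with the prior count (-1.05 to 0.25) and 3.14 of RORA (4.63 to 5.52). It had -2.36 of LHX2 (0.37 to 1.89) and -0.11 of RYR1 (ENSDARG00000023797, 3.05 to 4.85).

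Normal brain 2 and brain tumor 6 had photoreceptor list means of 3.61 (0.71 to 1.26 in the other normal brains) and 2.52 (-0.18 to 0.55 in the other tumors), and normal brain 2 had 3.55 log2 CPM of GNAT2 (1.02 to 1.61). Normal brain 4 had a glutamatergic list mean of 5.71 (5.94 to 6.12), 5.79 log2 CPM of OLIG2 (5.20 to 5.47) and 7.11 of RYR1 (ENSDARG00000023797, 7.39 to 7.62). Normal brain 11 had a neuropeptide list mean of 3.29 (3.86 to 4.16). Brain tumor 8 had 6.15 log2 CPM of ccl34b.8 (0.79 to 2.23), 0.77 of pth2 (-3.05, a count of 0, to -1.67) and 9.06 of UGT8 (10 to 10.66). Brain tumor 14 had 2.83 log2 CPM of c6.1 (5.04 to 6.61). Normal brain 1 had 4.70 log2 CPM of FOSB (3.91 to 4.23), normal brain 3 had a count of 0 of ifit8, which stands at -3.05 (-2.05 to -1.34, or 0.121 to 0.273 CPM, around the level of a count of 3), and normal brain 15 had 0.18 of c1qc (0.97 to 1.55).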

How the results depend on the processing

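The fits of libraries 1 to 8, of libraries 9 to 15 and without the 4 libraries in doubt were chosen only after the data were seen. All 63 named-gene results kept their direction and their side of the threshold under every setting in which they were tested (58 with the filter at 5 CPM). Apart from NRAS, SOX10 and OLIG2, these genes were named for small p-values or large changes in these same data. Their stability was thus largely set by the choice and says little about other genes. Between 6222 (filter at 5 CPM) and 9350 (no filter) genes were higher and 5441 to 7970 lower over the planned settings other than leaving out libraries, and leaving out 1 library gave 7589 to 8369 higher, 6240 to 6903 lower and 13 to 15 lists. Of genes at least 2-fold higher in brain tumor glmTreat, which tests against a log2 fold change of 1, gave 3960, and of genes at least 2-fold lower in brain tumor 3855. The scaling sets the balance of directions, with 7264 higher and 7252 lower under RLE factors, where the median of all genes moved from 0.21 to 0.02.

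With an estimated correlation camera called 0 lists, at the unchanged medians of the 14 lists (4.36, 1.04, -3.12, -3.32, -3.30, -2.83, -3.37, -3.10, 1.76, 2.42, 3.12, -1.06, -1.0 and -0.59). The construction of that setting is the cause, since the estimate (0.404 for cell cycle) replaces 0.01. The cause of the following changes was not tested. The myelin list came to pass at medians of 1.34 (RLE), 1.53 (upper quartile and no filter), 1.44 (library size), 1.42 (without the 50 largest genes), 1.33 (DESeq2), 1.32 (limma-voom) and 1.11 (libraries 9 to 15), and at 1.43 to 1.58 in the 6 fits without 1 library in which it passed (1.40 to 1.58 over all 15 of these fits, passing or not). Its adjusted p over the 4 scalings was 0.0287 to 0.0429. Radial glia came to pass at -0.74 (no filter), -0.83 (limma-voom) and -0.89 (libraries 1 to 8), and heat shock at 0.81 (no filter) and 0.80 (limma-voom). Erythrocyte was lost at -1.24 (filter at 5 CPM), -1.14 (DESeq2 and libraries 9 to 15) and -0.95 (without 4 libraries), ependyma at -1.45 (filter at 5 CPM), and oligodendrocyte precursor at 0.52 (limma-voom). Hypoxia was lost at -0.59 (libraries 9 to 15) and -0.57 (without 4 libraries), and at -0.66 without brain tumor 7 and -0.68 without brain tumor 14 (-0.69 to -0.58 over all fits without 1 library). The skin median ranged from -0.31 (without brain tumor 12) to 1.36 (without normal brain 4), and camera turned its direction for skin without brain tumor 12, for skin at -1.09 and muscle at 0.73 in libraries 1 to 8, and for mural cells at 0.48 in libraries 9 to 15. In libraries 9 to 15 the matrix list passed at 1.79 and muscle at 3.46, and neutrophil passed at 1.94 without 4 libraries.

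Library numbers 1 to 4 against 9 to 15 within normal brain gave 3 genes past the threshold in edgeR. At an unadjusted p below 0.05 there were 2268 of 18956, more than the share of 0.05 that chance gives. Numbers 5 to 8 against 12 to 14 within tumors gave 0 genes past the threshold and 624 of 19301 unadjusted, below that share. A difference by number within normal brain cannot be excluded, and normal brains 1, 2 and 4, with transcripts of other tissues, all have low numbers. No paired analysis was possible because each library has its own number. The pseudocount alternative planned for normalized values was not run, since counts were deposited. At these depths a count of 0 allows up to 0.220 CPM on the unscaled library sizes.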

Other observations

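Gene families defined by symbol were looked at only after the data were seen. Some of their members are also in the lists, such as the proteasome genes PSMB8, PSMB9, PSMB10, psmb12 and psmb13a in the interferon list. The per-list medians of the other splits were added after the number of called lists was seen, while the 4 counts of splits were planned. Cytosolic ribosomal protein genes rose in 76 of 77 cases with a median log2 fold change of 2.35, among them RPL29 (2.36 ± 0.10). Subunit genes of the proteasome, which degrades ubiquitin-tagged proteins, rose in 41 of 41 cases (median 1.54), with PSMA5 at 2.24 ± 0.11. All 7 tested subunit genes of the chaperonin CCT, which folds actin and tubulin, rose (median 1.68). Mitochondrial ribosomal protein genes rose in 61 of 73 cases with a median of 0.55, and in 41 under RLE factors and DESeq2, with MRPS34 falling (-0.41 ± 0.13). Genes of the respiratory chain and ATP synthase had a median of -0.12 (9 rose and 29 fell of 81) and of -0.31 under RLE factors, where 6 rose and 48 fell.

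Potassium channel genes, which set the excitability of neurons, fell in 73 of 84 cases (median -2.84), and 1 copy each of KCNH5 (ENSDARG00000043220), KCNJ10 (ENSDARG00000090815) and KCNK5 (ENSDARG00000023587) rose. Voltage-gated calcium channel genes fell in 27 of 32 cases (median -2.81), and the rising members were CACNG1 (ENSDARG00000008772, 3.06 ± 0.50) and CACNA1S (ENSDARG00000042552, 1.53 ± 0.57), both of the skeletal muscle channel, and cacna1fa. Chemokine genes, which attract leukocytes, rose in 19 of 25 cases (median 2.65), with ccl34a.4 at 7.01 ± 0.82 and cxcl11.4 at 5.61 ± 0.59, and CXCL14, cxcl12b and ccl44 fell. HOX genes, which pattern the hindbrain and trunk, rose in 1 (HOXB7) and fell in 4 of 21 cases (HOXC12, HOXB6, HOXC6 and HOXD3), with a median of -1.48. No family median changed sign under any setting run. NKX2-2 (ENSDARG00000053298), a transcription factor of oligodendrocyte precursors, rose from 16.1 ± 2.82 to 436 ± 171 CPM (log2 fold change 4.76 ± 0.24). It was written into the oligodendrocyte precursor list under symbols that found no match, so it was not counted or tested there.

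Against 99 other splits of the 15 libraries into 8 and 7, the real split gave the most genes higher in tumor (8370, highest other 4568). The same held for genes lower (6436, highest other 3326) and genes changed at least 2-fold (10071, highest other 4779). In each case 1 of 100 splits, the real one, gave as many, which is the smallest share that 100 splits can give. The highest other counts came from a split with 6 tumors in the group of 7. Every other split mixed tumors and normal brains, which puts their difference into the spread within groups. The counts thus show that the labelled groups differ, and not why. In 97 of the other splits edgeR called 0 genes. For the number of lists past the camera threshold, 76 of 100 splits gave at least the real 14, and the highest other gave 25. The other splits hold unequal shares of tumors in their groups, so part of the tumor difference stays between them. The count therefore cannot decide for or against chance, and it gives the list calls no support. The median of a list was larger in the real split than in all 99 others for 22 of the 33 lists. Among them were cell cycle (4.36, highest other 2.61) and pan-neuronal (-3.12, highest other 1.85 in size). Mixing the groups dilutes a difference between them, so a list that differs between tumor and normal brain tends to peak in the real split. These medians are thus no separate support for the list calls.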
